A study of Pimephales promelas with 64 samples.

How the data were processed

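The deposited tables covered RNA-seq of brain tissue from 63 adult fathead minnows, with 44624 coding sequences per sample under 26285 gene symbols, of which 13563 sequences (30.4%) carried only a locus number. The values were estimated counts per coding sequence, per the file headers, and the submitters' processing notes name FastQC 0.11.5, cutadapt 1.18 and kallisto 0.45.0. The estimated counts as deposited were neither normalized nor whole (46.5% were whole numbers exactly). The genome build and the authors' tool for differential expression are not given in the sources used here. The deposited table of all samples also held a sample presence fraction, which equalled the share of samples with an estimated count of at least 1 in every sequence (tolerance 1e-8). The authors' comparison tables give a log2 fold change and an adjusted p-value per sequence, per the file headers. These were used only to set the authors' counts of calls beside the counts computed here.

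Groups were sex by site as the labels give them, namely control, upstream and downstream, with 8, 11 and 12 female libraries and 8, 13 and 11 male libraries. Male downstream replicate 13 had no counts and was left out. Library totals ran from 11.6 to 126.5 M estimated counts with a median of 21.8 M, and 13 mitochondrially encoded sequences took a median of 11.2% to 12.6% of the counts by group. The lowest chi-square per degree of freedom between replicates was 24.6, so the spread between libraries was well above counting error. The p-values measure only the spread between these samples, because the labels do not say which fish shared a tank or cage or where the controls were kept. The labels give tanks at 19 to 23 °C.

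Counts were rounded and tested in edgeR 4.0.16 (R 4.3.3) with filterByExpr, TMM scaling and the quasi-likelihood F-test. Each pair of groups was fitted within 1 sex, and the interaction of sex with exposure was fitted over both sexes. A sequence was called at a Benjamini-Hochberg adjusted p under 0.05 over all sequences tested in a comparison. Standard errors are approximate, from the log2 fold change divided by the square root of F. Levels are means of library-scaled counts (CPM). Features were coding sequences, so a gene with several isoforms had several features, and sequences identical to another (8483) had their counts divided among them. Gene sums added the sequences of a symbol before testing.

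There were 33 lists of genes fixed by symbol, covering estrogen signalling, reproductive neuroendocrine genes, pituitary hormones, thyroid axis, aryl hydrocarbon receptor, xenobiotic metabolism, oxidative stress, metal response, heat shock, ER stress, glucocorticoid response, immediate early genes, circadian clock, appetite and hypothalamic peptides, monoamine systems, and GABA and glutamate transmission. The others were interferon and innate immunity, hypoxia, DNA damage, proliferation, sterol and fatty acid synthesis, respiratory chain, mitochondrially encoded genes and ribosomal proteins, and the marker lists of neurons, oligodendrocytes, radial glia and astroglia, microglia and macrophages, blood, muscle, liver, meninges and matrix, and eye and pineal. A list needed 3 tested members. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Each list was tested in 7 comparisons. Members were also adjusted over the list alone. A few members with other names in the tables, among them CYP1A (cytochrome P450 1A1), brain aromatase, metallothionein (mtbl) and hspa1b, were matched by description after the tables were seen.

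Named genes followed a rule. Among called sequences with a symbol or description and a mean log2 CPM of at least 0, the 8 largest rises and the 8 largest falls of each comparison and sex were named, with 1 sequence per gene. Up to 10 called list members with the smallest adjusted p and up to 8 sequences called in the same direction in both sexes were added. Brain aromatase, CYP1A, esr1, vtg1, metallothionein, hspa1b and fkbp5 were named whether called or not. Other list members are given as examples and were picked after their values were seen, as were the genes plotted. The grouping, comparisons, lists, naming rule and the first set of other settings were fixed before the data were examined.

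These other settings were DESeq2 1.42.0, its size factors within edgeR, limma voom with quality weights, no filter on low counts, a mean CPM of at least 1, the 3 groups of a sex in 1 fit, a replicate block, 1 surrogate variable (sva 3.50.0), removal of low-depth libraries, sums per gene and each library left out in turn. Settings added after the data were seen were the muscle marker sum as a covariate, removal of the 4 libraries over 2000 CPM in that sum, removal of the 1 library whose median correlation with the others lay under 0.817 (the lower quartile minus 1.5 interquartile ranges), counts thinned to 11.6 M per library, lists without members matched by description, the samples of the replicate block without the block, and low (1 to 8) or high (9 and over) replicate number as a covariate. Each exposure comparison was also fitted within either range of numbers, and the difference between the ranges was tested.

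The fits were tested on simulated data drawn from the real means and library sizes with known changes in 66, 67 and 67 genes at absolute log2 fold changes of 0.5, 1 and 2. For downstream against upstream edgeR recovered 13, 40 and 54 of these in females with 5 false calls, and 16, 41 and 53 in males with 3. For upstream against control it recovered 5, 29 and 55 in females with 7 false calls and 14, 33 and 50 in males with 1. For downstream against control it recovered 8, 31 and 55 in females with 2 false calls and 6, 35 and 47 in males with 4. DESeq2 made 36, 44 and 44 false calls in the 3 female comparisons and 36, 27 and 46 in the male ones, in the same order, and limma voom at most 5 in each.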

Results

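Gene expression was measured by RNA-seq in brains of adult fathead minnows (Pimephales promelas). Fish were exposed for 96 h at sites 100 m above (upstream) or 100 m below (downstream) an outfall of treated wastewater effluent, and untreated fish served as controls. Counts were present for 63 of the 64 labelled samples, all but male downstream replicate 13. Females comprised 8 control, 12 downstream and 11 upstream libraries, and males 8, 11 and 13. Median library totals were 21.1, 22 and 27.1 M in control, downstream and upstream females and 19.4, 23.6 and 27 M in males. Levels are given as mean ± SD of library-scaled counts (CPM) over the libraries of a group, and fold changes on the log2 scale with an approximate standard error (SE).

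The first comparison was downstream against upstream within each sex, so a difference may come from either site. In downstream females the cytosolic chaperone gene hsp90aa1.2 fell to 198 ± 36 CPM (n = 12) from 387 ± 141 CPM upstream (n = 11), a log2 fold change of -0.97 (SE 0.16, adjusted p = 0.026). The Polycomb-associated gene rybpa rose downstream, at 548 ± 70.8 against 377 ± 60.9 CPM (log2 fold change 0.53, SE 0.09, adjusted p = 0.026). Controls were at 536 CPM. The high mobility group gene hmgb3a rose from 389 ± 65.1 to 576 ± 73.8 CPM (log2 fold change 0.56, SE 0.09, adjusted p = 0.026), and the Jumonji-like gene LOC120484552 from 61.8 ± 21.2 to 114 ± 18.9 CPM (log2 fold change 0.88, SE 0.14, adjusted p = 0.026). The call of LOC120484552 ended without the libraries highest in muscle markers and with the muscle marker sum as a covariate.

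In females 8 of 33640 tested coding sequences changed, 5 up and 3 down. The other changes were in single sequences of genes with several. A sequence of eif3c, a translation initiation factor subunit, fell from 149 ± 28.9 to 73 ± 17.6 CPM (log2 fold change -1.04, SE 0.13, adjusted p = 0.0014), while the sum of the gene's sequences had a log2 fold change of 0.01. A sequence of ss18, a chromatin remodelling subunit, fell by 0.61 (SE 0.1, adjusted p = 0.026), and the summed gene, at -0.25, was not called. Sequences of poldip2 (0.45) and zc2hc1a (0.35) rose, with gene sums of 0.08 and -0.04.

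The heat shock list, 19 tested chaperones and their regulators, was lower in downstream than in upstream females, with a median log2 fold change of -0.277. Of its members 1 fell with adjustment over all features and 10 were lower when adjusted over the list alone, with none higher. Besides hsp90aa1.2 these included hspa4a at 55.9 against 80.8 CPM (adjusted p = 0.063 over all features), the collagen chaperone serpinh1b at 15.3 against 37.7 CPM (adjusted p = 0.067) and hsp70.3 at 17.9 against 33.2 CPM (adjusted p = 0.068). The list test gave an adjusted p of 2.29e-11, and adjusted p = 0.0418 with an estimated correlation. Among replicates numbered 9 and over (8 downstream, 7 upstream) the list median was -0.35 (adjusted p = 7.6e-15, and adjusted p = 0.0182 with an estimated correlation). Among those numbered 1 to 8 (4 and 4) it was -0.13 (adjusted p = 0.0688). The test of the difference between these ranges gave a median of -0.23 (adjusted p = 0.000148, and adjusted p = 0.241 with an estimated correlation). The summed list had medians of 4360 CPM downstream and 4790 CPM upstream in the later numbers, and of 4120 and 4140 CPM in the earlier ones. The division at 8 was chosen after the values were seen, and the labels do not say what the numbers stand for.

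The sterol and fatty acid synthesis list (27 tested) had a median of 0.212, with 0 members called over all features and 3 higher when adjusted over the list alone, scdb, tm7sf2 and hmgcs1. Its list test gave an adjusted p of 1.4e-09, and adjusted p = 0.2 with an estimated correlation. Muscle markers had a median of -6.13 in the same comparison, with 12 of 13 lower when adjusted over the list alone and 0 called over all features (adjusted p = 2.67e-07 for the list, and adjusted p = 0.821 with an estimated correlation). The summed muscle markers were at 24500 and 2569 CPM in upstream replicates 1 and 11 and lay between 179 and 302 CPM in the downstream females, while the group medians were 261 CPM upstream and 242 CPM downstream. Liver markers had a median of -2.48, with 7 of 11 lower when adjusted over the list alone (adjusted p = 0.0256, and adjusted p = 0.821 with an estimated correlation). Their sum was 6570 CPM in upstream replicate 11, while the group medians were 496 CPM upstream and 501 CPM downstream. Meningeal and matrix markers had a median of -0.533, with 1 of 14 lower, rbp4 (adjusted p = 0.0444, and adjusted p = 0.821 with an estimated correlation). The egg yolk precursor gene vtg1, a classic marker of estrogen exposure in fish, averaged 10.5 ± 20.2 CPM downstream and 402 ± 1230 CPM upstream and was not called (log2 fold change -5.28, SE 1.52, adjusted p = 0.2).

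Chaperone genes were lower in downstream males too. The gene hsp90aa1.2 fell from 425 ± 144 CPM upstream (n = 13) to 210 ± 45.2 CPM downstream (n = 11), a log2 fold change of -1.01 (SE 0.18, adjusted p = 0.028). Expression of serpinh1b fell from 46.3 ± 20.4 to 16.3 ± 7.23 CPM (log2 fold change -1.51, SE 0.28, adjusted p = 0.034). The co-chaperone gene dnaja fell from 29 ± 13.4 to 9.77 ± 3.33 CPM (log2 fold change -1.57, SE 0.27, adjusted p = 0.023), and hspa4a from 93.9 ± 23.4 to 59.7 ± 8.88 CPM (log2 fold change -0.65, SE 0.12, adjusted p = 0.039). A sequence of hsf1, the transcription factor that drives the heat shock response, fell from 14.9 ± 4.71 to 7.59 ± 1.83 CPM (log2 fold change -0.97, SE 0.18, adjusted p = 0.032).

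In males rybpa again rose, from 350 ± 44.4 to 522 ± 91.6 CPM (log2 fold change 0.57, SE 0.09, adjusted p = 0.012), as did kiaa1143 (log2 fold change 0.47, SE 0.08, adjusted p = 0.028). A total of 25 of 33825 tested sequences changed, 13 up and 12 down. Several of these were single sequences whose gene sums were not called. A sequence of cirbpa, a cold-inducible RNA-binding protein, rose from 40.6 ± 12.1 to 73.6 ± 14.6 CPM (log2 fold change 0.86, adjusted p = 0.028, gene sum 0.27), and one of the RNA-binding protein gene khdrbs1a rose by 0.44 (adjusted p = 0.0058, gene sum -0.02). The eif3c sequence called in females fell by 0.88 in males (adjusted p = 0.039, gene sum 0.05). LOC120474467, described as a poly ADP-ribose protein with the description breaking off there, rose by 1.1 (gene sum 0.04), celf3b by 0.55 (gene sum 0) and the membrane progestin receptor gene paqr6 by 0.54 (gene sum -0.09). The amino acid transporter gene slc43a2a rose by 0.48, again without a called gene sum. LOC120486364 fell by 1.05 (gene sum -0.11) and LOC120488195 fell by 0.79 (gene sum -0.14).

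Of the 19 heat shock members in males, 3 fell over all features and 10 were lower when adjusted over the list alone, with none higher and a median of -0.308. The list test gave an adjusted p of 3.76e-14, and adjusted p = 0.0746 with an estimated correlation. Its median was -0.35 among replicates numbered 9 and over (7 downstream, 9 upstream, adjusted p = 2.89e-18, and adjusted p = 0.00213 with an estimated correlation). It was -0.2 among those numbered 1 to 8 (4 and 4, adjusted p = 4.56e-05, and adjusted p = 0.0492 with an estimated correlation). The test of the difference between the ranges gave a median of -0.06 (adjusted p = 0.0204, and adjusted p = 0.311 with an estimated correlation). The gene hsp90aa1.2 differed by -1.18 (SE 0.11) in the later numbers and by -0.33 (SE 0.19) in the earlier ones, against -1.14 (SE 0.14) and -0.54 (SE 0.13) in females. The summed list had medians of 4620 CPM downstream and 5460 CPM upstream in the later numbers, and of 4130 and 4330 CPM in the earlier ones.

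The immediate early gene list (23 tested) had a median of 0.175 in males with 0 members called over all features or over the list alone (adjusted p = 0.00343, and adjusted p = 0.854 with an estimated correlation). Its direction turned with the replicate number. The median was 0.88 in males and 0.67 in females numbered 1 to 8, and -0.19 and -0.33 in later numbers. The difference between the ranges passed with an estimated correlation in males (adjusted p = 0.000815) and females (adjusted p = 0.00611). The sterol list in males had a median of 0.0994 and likewise 0 called members (adjusted p = 0.0321, and adjusted p = 0.855 with an estimated correlation). Blood markers had a median of 0.397 (adjusted p = 0.0197, and adjusted p = 0.425 with an estimated correlation), meningeal markers 0.127 (adjusted p = 0.0488, and adjusted p = 0.855 with an estimated correlation) and liver markers 0.563 (adjusted p = 0.0235, and adjusted p = 0.674 with an estimated correlation), with no member of these 3 lists called over all features or adjusted over the list alone. Muscle markers were not called as a list in males (median -1.38, adjusted p = 0.462).

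**Figure D1:**
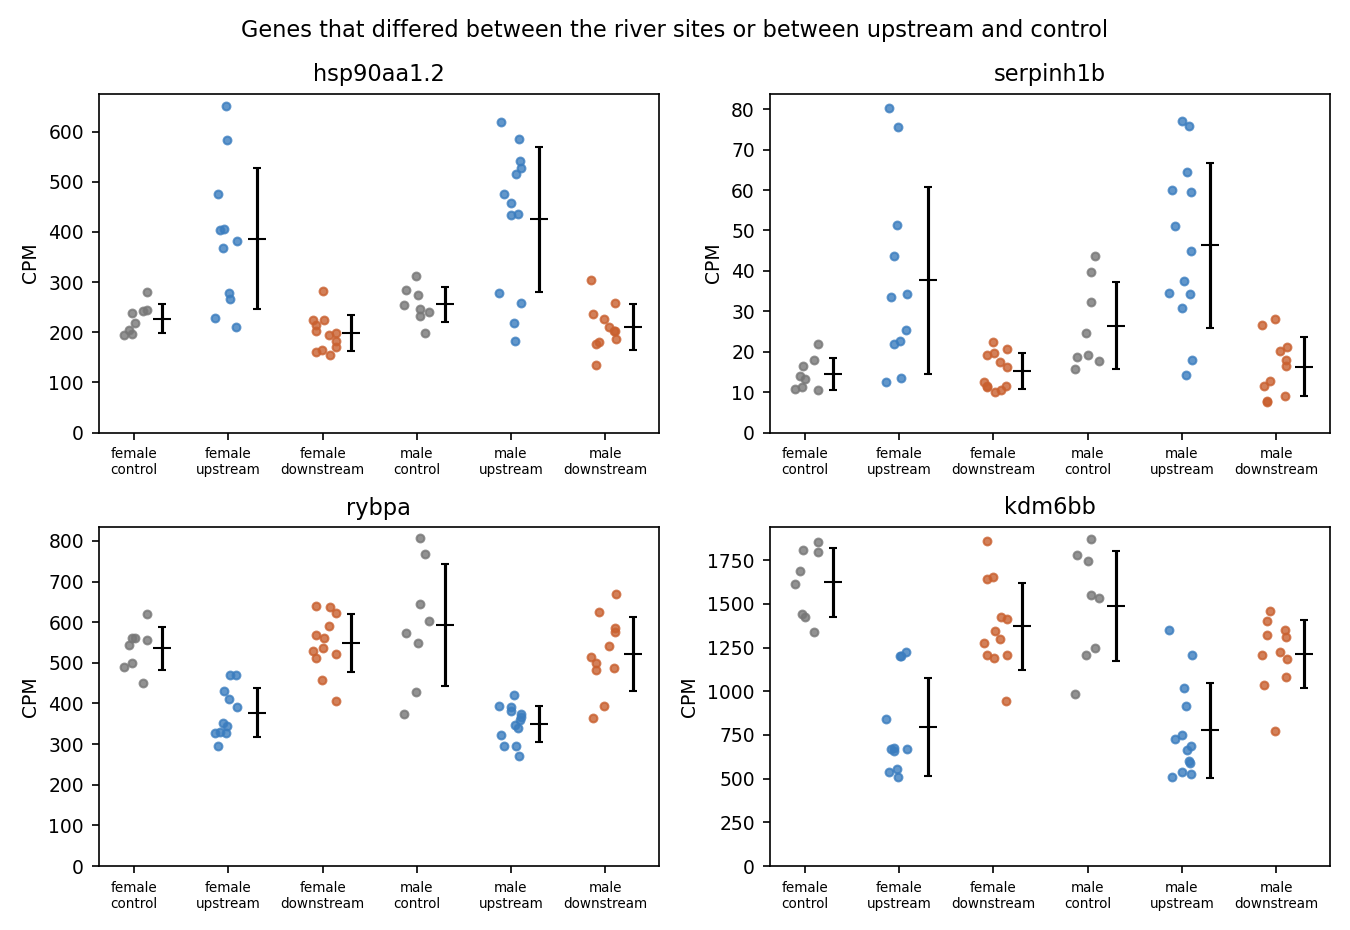
Levels of hsp90aa1.2, serpinh1b, rybpa and kdm6bb in CPM by group; points are libraries and bars the mean ± SD. hsp90aa1.2 averaged 387 CPM in upstream and 198 CPM in downstream females, and 425 and 210 CPM in the corresponding males.

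None of the fixed marker genes was called by edgeR between downstream and upstream fish. CYP1A (LOC120484856), the cytochrome P450 induced through the aryl hydrocarbon receptor, differed by -0.3 in females (SE 0.24, adjusted p = 0.83) and by -0.61 in males (SE 0.24, adjusted p = 0.56). The list of this receptor did not pass in females (median -0.125, adjusted p = 0.83) or in males (median -0.605, adjusted p = 0.0579). Brain aromatase (LOC120477771), which makes estrogens in radial glia, differed by -0.04 and -0.15, the estrogen receptor gene esr1 by -0.36 and -0.16, the metallothionein gene mtbl by -0.17 and 0.05, the heat shock gene hspa1b by -0.61 and -0.08, and the glucocorticoid-responsive gene fkbp5 by 0.06 and 0.17. The smallest adjusted p among these was 0.55, leaving vtg1 aside. When each library was left out in turn, the number of called sequences ranged from 1 to 89 in females and from 5 to 78 in males, so these counts depended on single libraries; the other tools also gave different counts, 259 and 213 by DESeq2 and 63 and 98 by limma voom. With low or high replicate number as a covariate they were 103 and 113.

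Comparisons with controls followed, mixing exposure with any difference in place or handling. CYP1A had the smallest adjusted p of all called sequences in both sexes at both sites. It averaged 0.84 ± 0.341 CPM in control females (n = 8) and 0.669 ± 0.348 CPM in control males (n = 8). Upstream it reached 18 ± 9.72 CPM in females (21.5-fold, log2 fold change 4.43, SE 0.35, adjusted p = 3.2e-06) and 16.1 ± 8.84 CPM in males (24.2-fold, log2 fold change 4.6, SE 0.43, adjusted p = 1.8e-05). Downstream it reached 14.7 ± 4.76 CPM in females (17.5-fold, log2 fold change 4.13, SE 0.25, adjusted p = 1.7e-08) and 10.6 ± 1.96 CPM in males (15.8-fold, log2 fold change 3.98, SE 0.29, adjusted p = 8.8e-07). Controls lay between 0.156 and 1.59 CPM and exposed fish between 5.16 and 38.6 CPM, without overlap.

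**Figure D2:**
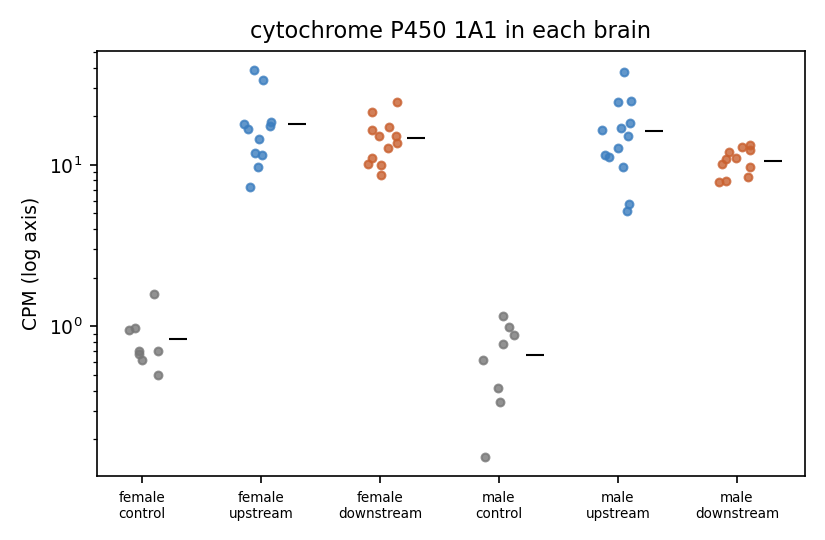
CYP1A (LOC120484856) in CPM on a log axis by group; each point is a library and the bar is the mean. Control libraries lie between 0.156 and 1.59 CPM, and upstream and downstream libraries between 5.16 and 38.6 CPM.

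The aryl hydrocarbon receptor list held 3 tested members, and CYP1A was the only one to pass, over all features and adjusted over the list alone, in each of the 4 comparisons with controls. The receptor repressor gene ahrra was at 1.91 CPM in upstream and 1.76 CPM in downstream females against 0.539 CPM in controls (adjusted p = 0.64 and 0.68), and the receptor gene ahr2 differed by 0.03 and 0.1. The list test passed in upstream females (median 1.78, adjusted p = 1.88e-10), downstream females (median 1.66, adjusted p = 5.8e-17), upstream males (median 1.52, adjusted p = 2.68e-09) and downstream males (median 0.342, adjusted p = 2.88e-11). It also passed with an estimated correlation, at adjusted p = 0.000102, 2.37e-06, 0.000695 and 6.69e-05. These list tests add little to the calls of CYP1A, which was matched by description after the tables were seen. Without it the list had 2 tested members, too few for a test.

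In upstream females 3 immediate early genes, which neurons switch on within minutes of stimulation, were called against control females. The AP-1 gene fosb rose from 3.83 ± 1.81 to 14.2 ± 4.2 CPM (log2 fold change 1.89, SE 0.29, adjusted p = 0.034). The orphan nuclear receptor genes nr4a3 and nr4a1 rose as well, nr4a1 from 8.3 ± 1.99 to 18.9 ± 6.3 CPM (log2 fold change 1.19, SE 0.21, adjusted p = 0.048) and nr4a3 by 1.45 (SE 0.25, adjusted p = 0.048). The corepressor gene nab1a rose from 19.2 ± 3.24 to 42.3 ± 14.1 CPM (log2 fold change 1.14, SE 0.2, adjusted p = 0.049). The histone H3K27 demethylase gene kdm6bb, whose counts were divided evenly among 4 identical sequences, fell from 1620 ± 199 to 794 ± 280 CPM per sequence (log2 fold change -1.03, SE 0.17, adjusted p = 0.034).

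Among the remaining calls in upstream females, rybpa fell from 536 ± 52.9 to 377 ± 60.9 CPM (log2 fold change -0.51, SE 0.09, adjusted p = 0.049) and oga, the enzyme that removes O-GlcNAc from proteins, from 116 ± 11.6 to 87.9 ± 8.21 CPM (log2 fold change -0.41, SE 0.07, adjusted p = 0.039). The methyltransferase gene bhmt rose from 46.8 ± 14.5 to 91.1 ± 15.8 CPM, the keratin gene krt18a.1 from 119 ± 25.3 to 203 ± 32.1 CPM and rergla from 9.4 ± 1.53 to 14.9 ± 2.67 CPM. In all, 16 of 34494 tested sequences changed, 10 up and 6 down, and leaving out 1 library gave 1 to 28. Apart from CYP1A, each of these named calls was lost with no filter on low counts, where 1 sequence was called, and after removal of the low-depth library, control replicate 15, where 1 was called. All but CYP1A and bhmt were also lost without the libraries highest in muscle markers, where 2 sequences were called.

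Of the 23 immediate early genes in upstream females, 3 rose over all features and 10 were higher when adjusted over the list alone, with a median of 0.477 (adjusted p = 4.17e-14, and adjusted p = 0.0686 with an estimated correlation). The list median was 0.64 among replicates numbered 9 and over (adjusted p = 3.84e-13, and adjusted p = 0.162 with an estimated correlation) and 0.1 among those numbered 1 to 8 (adjusted p = 0.153). The difference between the ranges had adjusted p = 0.0101, and adjusted p = 0.557 with an estimated correlation. The heat shock list had 0 of 19 members called over all features and 11 higher when adjusted over the list alone, with a median of 0.31. Examples were serpinh1b at 37.7 against 14.6 CPM and hsp90aa1.2 at 387 against 227 CPM, and the list test passed at adjusted p = 1.29e-11 and with an estimated correlation at adjusted p = 0.0286. The sterol list had 0 members called over all features and 6 higher when adjusted over the list alone, among them hmgcs1 at 94.7 against 54.4 CPM (list median 0.264, adjusted p = 1.17e-07, and adjusted p = 0.126 with an estimated correlation). The glucocorticoid response list (15 tested) had 0 called members over all features and 3 higher when adjusted over the list alone, crhb, hsd11b2 and ddit4, with a median of 0.48 (adjusted p = 0.00223, and adjusted p = 0.0273 with an estimated correlation).

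Markers of other tissues moved in the same comparison. Blood markers had a median of -0.837 in upstream females, with 2 of 5 lower when adjusted over the list alone, the heme synthesis gene alas2 and the anion exchanger gene slc4a1a (adjusted p = 3.41e-05, and adjusted p = 0.0821 with an estimated correlation). Eye and pineal markers had a median of -0.408, with 2 of 10 lower when adjusted over the list alone (adjusted p = 0.0219, and adjusted p = 0.451 with an estimated correlation), and microglial markers a median of -0.257 with 0 of 16 called (adjusted p = 0.0219, and adjusted p = 0.64 with an estimated correlation). Proliferation genes had a median of -0.327 with 0 of 24 called (adjusted p = 0.0111, and adjusted p = 0.642 with an estimated correlation). The muscle list had a median of 1.3 while its test pointed down (adjusted p = 0.617), and the reason was not tested. Liver markers had a median of 0.512 (adjusted p = 0.0836).

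Upstream males had raised expression of cholesterol synthesis genes. Expression of hmgcs1, which encodes an early enzyme of the mevalonate pathway, rose from 56.9 ± 7.26 CPM in controls (n = 8) to 125 ± 33.4 CPM (n = 13), a log2 fold change of 1.13 (SE 0.15, adjusted p = 0.0019). The rate-limiting reductase gene hmgcra rose from 86.5 ± 24 to 163 ± 36.4 CPM (log2 fold change 0.9, SE 0.16, adjusted p = 0.014). Further rises were in lss (0.78), fdft1 (0.68) and the squalene monooxygenase gene sqlea (1.06). The list gave 6 rises among 27 members over all features, and 15 higher and 1 lower, the desaturase gene scd, when adjusted over the list alone. Its median was 0.417, and its test passed at adjusted p = 6.31e-22 and with an estimated correlation at adjusted p = 0.00813.

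Of 34400 sequences tested in upstream males 112 changed, 67 up and 45 down. Transcripts of fosb rose from 3.17 ± 1.84 to 11.5 ± 4.59 CPM (log2 fold change 1.84, SE 0.32, adjusted p = 0.014), nab1a by 1.4 (SE 0.25, adjusted p = 0.019) and the replication licensing gene mcm4 from 6.53 ± 1.91 to 15.1 ± 5.74 CPM (log2 fold change 1.19, SE 0.25, adjusted p = 0.04). The clock repressor gene nr1d1 fell by 1.38 (SE 0.28, adjusted p = 0.037), and the clock-linked gene nfil3-6 rose from 26.9 ± 3.39 to 46 ± 8.61 CPM (log2 fold change 0.76, SE 0.11, adjusted p = 0.0047). As in females, rybpa fell, from 594 ± 150 to 350 ± 44.4 CPM (log2 fold change -0.77, SE 0.12, adjusted p = 0.0065), kdm6bb fell from 1490 ± 315 to 776 ± 270 CPM per sequence (log2 fold change -0.95, SE 0.18, adjusted p = 0.021) and oga fell by 0.34 (adjusted p = 0.039). Also falling were lipid peroxide reductase gene gpx4a (-0.67), muscle ubiquitin ligase gene fbxo32 (-1.33) and parvalbumin-2, LOC120490614 (-7.01). The last rested on 1 control at 642 CPM. A p2rx3b (purinergic receptor) sequence fell by 2.03, without a called gene sum. LOC120479248, described as an androgen-dependent TFPI-regulating protein, rose by 2.48, the co-chaperone gene dnaja by 1.3 and purg by 1.16. Falls of single sequences whose gene sums were not called were those of hint3 (-1.29, gene sum -0.22), si:dkey-22n8.3 (-1.22, gene sum -0.88) and LOC120474467 (-1.05, gene sum -0.14). A sequence of hdac9b was at 3.79 ± 3.45 against 0.0179 ± 0.0505 CPM (adjusted p = 0.021), with a gene sum of 0.24 that was not called.

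The heat shock list in upstream males had 3 rises over all features, hspa4a (0.65), dnajb1a (0.54) and stip1 (0.37), and 11 of 19 higher when adjusted over the list alone, with a median of 0.36 (adjusted p = 4.09e-10, and adjusted p = 0.0874 with an estimated correlation). In replicates numbered 9 and over hsp90aa1.2 was higher upstream than in controls by 0.86 (SE 0.13) in males and 1.01 (SE 0.16) in females. In those numbered 1 to 8 it differed by -0.04 (SE 0.14) and 0.18 (SE 0.15). The difference between the ranges was called in both sexes (0.9, SE 0.19, adjusted p = 0.015, and 0.86, SE 0.24, adjusted p = 0.045). Immediate early genes had 1 rise over all features and 10 of 23 higher when adjusted over the list alone, with a median of 0.442 (adjusted p = 1.29e-09, and adjusted p = 0.159 with an estimated correlation). Their median was 0.48 among replicates numbered 9 and over (adjusted p = 2.12e-07, and adjusted p = 0.261 with an estimated correlation) and 0.13 among those numbered 1 to 8 (adjusted p = 0.503). The difference between the ranges did not pass (adjusted p = 0.0925). Proliferation genes had 1 rise over all features and 9 of 24 higher when adjusted over the list alone, 5 of them subunits of the MCM helicase, with a median of 0.43 (adjusted p = 1.19e-11, and adjusted p = 0.221 with an estimated correlation). The glucocorticoid list had a median of 0.0763 (adjusted p = 0.115).

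Beside these groups, muscle markers had a median of -2.84 in upstream males, with 0 called over all features and 10 of 14 lower when adjusted over the list alone (adjusted p = 4.62e-06, and adjusted p = 0.467 with an estimated correlation). Meningeal markers had a median of -0.687 with 0 of 14 called (adjusted p = 1.76e-05, and adjusted p = 0.233 with an estimated correlation). Blood markers had a median of -1.08 with alas2 lower when adjusted over the list alone (adjusted p = 0.000943, and adjusted p = 0.159 with an estimated correlation). With the muscle marker sum as a covariate the count was 29, and without the libraries highest in muscle markers 46; the calls of nab1a, mcm4, gpx4a, oga, kdm6bb and sqlea were among those that ended in the first of these, and those of mcm4, oga, kdm6bb and sqlea among those that ended in the second. Leaving out single libraries gave 29 to 173 calls.

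Downstream females also had raised expression of sterol synthesis genes. Expression of hmgcs1 rose from 54.4 ± 7.18 CPM (n = 8) to 141 ± 32.9 CPM (n = 12), a log2 fold change of 1.37 (SE 0.13, adjusted p = 2e-05), and sqlea from 33.5 ± 6.95 to 63.9 ± 16.9 CPM (log2 fold change 0.92, SE 0.16, adjusted p = 0.011). Of 27 list members 11 rose over all features, including idi1 (0.73), hmgcra (0.84), sc5d (0.66), dhcr7 (0.45) and fdps (0.6), and 19 were higher when adjusted over the list alone. None was lower. The list median was 0.457, and its test passed at adjusted p = 6.86e-33 and with an estimated correlation at adjusted p = 0.000372.

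Immediate early genes rose in downstream females too. Levels of fosb rose from 3.83 ± 1.81 to 13.9 ± 4.55 CPM (log2 fold change 1.85, SE 0.3, adjusted p = 0.0083), of nr4a1 from 8.3 ± 1.99 to 23.8 ± 12.2 CPM (log2 fold change 1.51, SE 0.27, adjusted p = 0.014), of nr4a3 by 1.3 (SE 0.21, adjusted p = 0.0067) and of fosaa, the c-Fos gene, by 0.78 (SE 0.14, adjusted p = 0.014). These were the 4 members called over all features, and 12 of 23 were higher when adjusted over the list alone. The list had a median of 0.492 (adjusted p = 5.8e-17) and passed with an estimated correlation (adjusted p = 0.0187). Here the larger median was in numbers 1 to 8, at 0.96, with 0.3 in later numbers (difference between the ranges adjusted p = 0.00144, and adjusted p = 0.491 with an estimated correlation). The glucocorticoid list had 0 members called over all features and 2 higher when adjusted over the list alone, crhb and per1b, with a median of 0.282 (adjusted p = 0.014, and adjusted p = 0.0497 with an estimated correlation). The heat shock list did not pass (median 0.112, adjusted p = 0.206), with 1 member, hsf1, lower over all features at -0.41 (adjusted p = 0.02).

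Other rises in downstream females were those of LOC120481843 (1.3, SE 0.16, adjusted p = 0.0012), the potassium channel gene kcnk3a (1.02), the endosomal sorting gene vps37bb (0.9) and a sodium pump subunit gene, LOC120460487, at 577 ± 69.6 against 414 ± 57.3 CPM (log2 fold change 0.47, SE 0.09, adjusted p = 0.017). A sequence of LOC120473937 rose by 1.56, with a gene sum of 0.29 that was not called. The largest falls were in muscle genes. Parvalbumin gene pvalb3 fell from 97.3 ± 143 to 2.08 ± 2.61 CPM (log2 fold change -5.56, SE 1.01, adjusted p = 0.014) and creatine kinase gene ckmb from 163 ± 203 to 7.71 ± 6.94 CPM (log2 fold change -4.41, SE 0.74, adjusted p = 0.01). Fast myosin heavy chain genes LOC120469742, LOC120469713 and LOC120463592 fell with log2 fold changes of -7.08, -6.37 and -5.87. The parvalbumins LOC120490614 and LOC120489681 were at -6.75 and -5.65, mylpfa at -5.7, and acta1b, actc1b and ckma at -4.57, -4.27 and -4.16. With limma voom or with the 3 groups in 1 fit most of these muscle calls ended. A rhodopsin-like gene, LOC120481127, fell by 6.52 (SE 1.1, adjusted p = 0.011). It stood at 114, 56.5 and 37.1 CPM in control replicates 9, 16 and 12 and at 3.09 CPM or less in the other controls.

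The muscle list had 9 falls over all features and 12 of 14 lower when adjusted over the list alone (median -4.56, adjusted p = 4.05e-24, and adjusted p = 0.0187 with an estimated correlation). Summed muscle markers had a median of 910 CPM in control females and 242 CPM in downstream females. Eye and pineal markers had 2 falls over all features, the photoreceptor genes pde6gb and arr3a, and 3 of 10 lower when adjusted over the list alone, with a median of -0.444 (adjusted p = 0.00398, and adjusted p = 0.184 with an estimated correlation). Their sum was 221, 158 and 91.7 CPM in control replicates 9, 16 and 12 and at most 31.1 CPM in the other 5 controls, and the group medians were 27 CPM in controls and 21.6 CPM downstream. Blood markers had a median of -0.434, with 2 of 5 lower when adjusted over the list alone (adjusted p = 0.00614, and adjusted p = 0.184 with an estimated correlation). Liver markers had a median of -1.55 while their test pointed up (adjusted p = 0.881), and proliferation genes did not pass (median -0.0523, adjusted p = 0.965). In all, 126 of 34299 sequences changed, 74 up and 52 down, and leaving out 1 library gave 56 to 126. With the muscle marker sum as a covariate the count was 4; CYP1A and hmgcs1 were still called, and the other named genes were not.

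**Figure D3:**
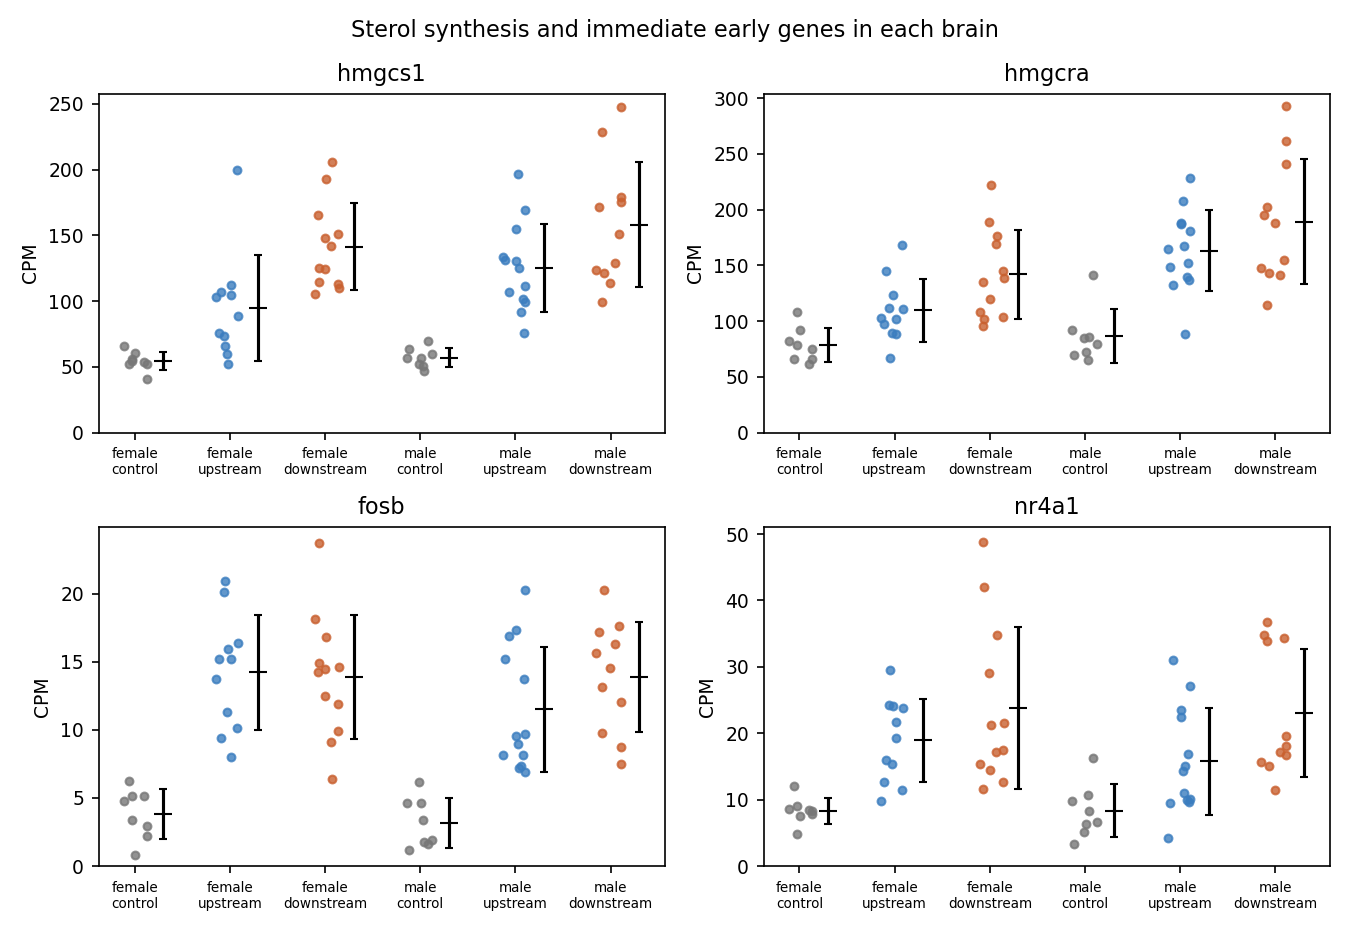
Levels of hmgcs1, hmgcra, fosb and nr4a1 in CPM by group; points are libraries and bars the mean ± SD. hmgcs1 averaged 54.4 CPM in control and 141 CPM in downstream females, and 56.9 and 158 CPM in the corresponding males.

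In downstream males 171 of 33836 sequences changed, 108 up and 63 down, and leaving out 1 library gave 65 to 207. The activity-regulated transcription factor gene npas4a rose from 87.7 ± 25.8 CPM (n = 8) to 274 ± 77.2 CPM (n = 11), a log2 fold change of 1.63 (SE 0.2, adjusted p = 0.0014), and fosb from 3.17 ± 1.84 to 13.9 ± 4.05 CPM (log2 fold change 2.11, SE 0.31, adjusted p = 0.0044). In the sterol pathway hmgcs1 rose from 56.9 ± 7.26 to 158 ± 47.7 CPM (log2 fold change 1.46, SE 0.16, adjusted p = 0.00041) and hmgcra from 86.5 ± 24 to 189 ± 56.3 CPM (log2 fold change 1.11, SE 0.18, adjusted p = 0.01). The clock-linked genes nfil3-6 (0.95, SE 0.13, adjusted p = 0.0033), ciarta (1.61, SE 0.34, adjusted p = 0.037) and si:ch211-132b12.7, a CLOCK-interacting pacemaker gene (1.56, SE 0.34, adjusted p = 0.047), rose as well.

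Further rises in downstream males were those of nr4a1 (1.46), fosaa (0.7), lss (0.85), fdft1 (0.87), LOC120481843 (1.26), vps37bb (0.94) and LOC120460487 (0.55). A sequence of bcl9, a Wnt pathway cofactor, was at 3.18 ± 2.68 CPM downstream and 0 in every control (adjusted p = 0.032, gene sum -0.04). It was at least 159-fold higher, against a floor of 3 counts over the control group, or 0.0199 CPM. Muscle genes fell again, pvalb3 from 93.2 ± 227 to 2.07 ± 1.65 CPM (-5.56, SE 1.11, adjusted p = 0.032). ckmb fell from 240 ± 477 to 11.2 ± 8.04 CPM (-4.45, SE 0.95, adjusted p = 0.04). Replicate 2 held most of both control levels, at 654 and 1400 CPM. Others were LOC120469713 at -6.35, LOC120489681 at -5.48, LOC120460301 at -5.2, ckma at -4.57, atp2a1l at -4.43 and acta1b at -4.21. A tropomyosin sequence, tpma, was at -5.06, without a called gene sum. With limma voom these muscle calls ended.

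Immediate early genes had 6 rises over all features in downstream males and 15 of 23 higher when adjusted over the list alone, with a median of 0.534 (adjusted p = 1.39e-19) that passed with an estimated correlation (adjusted p = 0.00712). The median was 0.89 in numbers 1 to 8 and 0.29 in later ones, and the difference between the ranges passed with an estimated correlation (adjusted p = 0.0301). The sterol list had 6 rises over all features and 16 of 27 higher when adjusted over the list alone, with a median of 0.445 (adjusted p = 1.58e-21, and adjusted p = 0.0121 with an estimated correlation). Proliferation genes had 1 rise over all features, mcm4, and 13 of 24 higher when adjusted over the list alone (median 0.57, adjusted p = 6.11e-15, and adjusted p = 0.175 with an estimated correlation). The glucocorticoid list had 0 members called over all features, and 5 higher and 1 lower when adjusted over the list alone, with a median of 0.341 (adjusted p = 0.00147, and adjusted p = 0.174 with an estimated correlation). The heat shock list did not pass (median 0.0185, adjusted p = 0.868).

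The muscle list had 6 falls over all features and 12 of 14 lower when adjusted over the list alone (median -4.32, adjusted p = 2.09e-08, and adjusted p = 0.366 with an estimated correlation). Summed muscle markers had a median of 375 CPM in control males, with 7630 CPM in control replicate 2, and 238 CPM in downstream males. Meningeal markers had a median of -0.508 with 0 of 14 called (adjusted p = 0.00901, and adjusted p = 0.645 with an estimated correlation), and microglial markers a median of -0.358 with 0 of 16 called (adjusted p = 0.00326, and adjusted p = 0.645 with an estimated correlation). Without the libraries highest in muscle markers the count was 78, and with the muscle marker sum as a covariate 17. The calls of CYP1A, fosb, npas4a, hmgcs1, nfil3-6 and LOC120481843 held in both settings, those of hmgcra, lss, fdft1 and fosaa ended with the covariate, and those of nr4a1, ciarta, si:ch211-132b12.7, bcl9 and the named muscle genes other than acta1b ended in both.

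**Figure D4:**
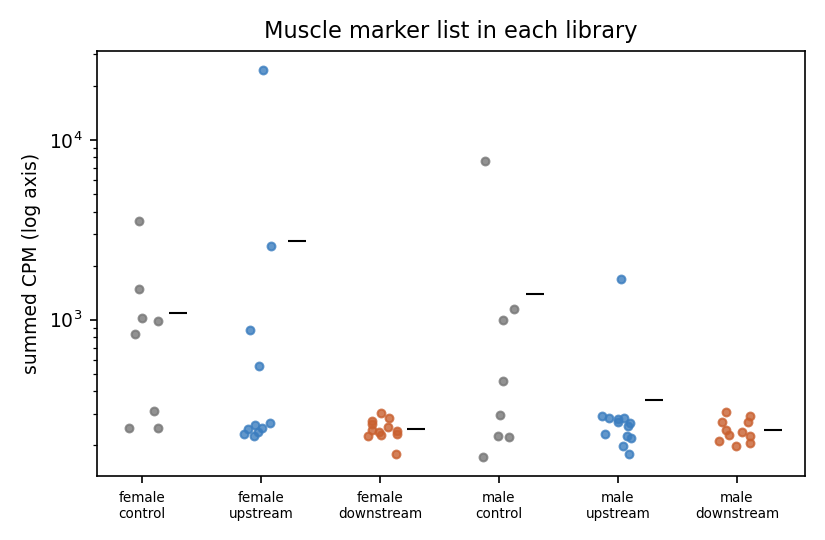
Summed CPM of the muscle marker list on a log axis by group; each point is a library and the bar is the mean. Downstream females lie between 179 and 302 CPM and control females between 251 and 3560 CPM, while 1 upstream female lies at 24500 CPM.

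The fixed marker genes other than CYP1A were not called against controls at either site. Brain aromatase was at 1560 ± 605 CPM in upstream and 1520 ± 522 CPM in downstream females against 830 ± 405 CPM in controls (log2 fold change 0.91, SE 0.5, adjusted p = 0.67, and 0.87, SE 0.36, adjusted p = 0.48), and differed by 0.15 and -0.01 in males. The estrogen receptor gene esr1 differed by 0.62 and 0.25 in females and 0.57 and 0.4 in males, and mtbl by 0.18 and 0.01 in females and -0.39 and -0.34 in males. The gene hspa1b differed by 0.72 and 0.12 in females and -0.63 and -0.71 in males. Vitellogenin gene vtg1 differed by 4.14 (SE 1.99, adjusted p = 0.6) and -1.15 in females, with 1 upstream female at 4120 CPM, and was too low for testing in males, where every library lay at or below 1.43 CPM. Expression of fkbp5 differed by 0.65 and 0.7 in females and by 1.24 (SE 0.4, adjusted p = 0.23) and 1.41 (SE 0.48, adjusted p = 0.21) in males, where DESeq2 called it at 1.23 and 1.41.

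Between downstream and upstream fish, 1 sequence rose in both sexes (rybpa, 0.002 expected for independent lists). Both had 2 falls (eif3c and hsp90aa1.2, 0.0011 expected). Between upstream and control fish, 3 rose in both (CYP1A, fosb and nab1a, 0.02 expected). Both had falls in 6 sequences of 3 genes (kdm6bb, oga and rybpa, 0.008 expected). Between downstream and control fish, 25 sequences of 23 genes rose in both (0.24 expected), including hmgcs1, sqlea, hmgcra, fdft1, fosb and nr4a1. Both had falls in 14 sequences of 13 genes, mostly muscle genes (0.095 expected). No p-value is given for these overlaps, because sequences, such as those of kdm6bb, muscle and sterol genes, are not independent. Fish of both sexes also shared the sites, so a factor of a site could act on both.

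Tests of the difference between the sexes called few features. The interaction of sex with exposure called 1 of 36789 sequences for downstream against upstream (LOC120486462, a fast myosin heavy chain), and 5 of 37154 for upstream against control, including the crystallin gene crygn1. For downstream against control edgeR called 0 of 36947, with 1459 at an unadjusted p under 0.05, while DESeq2 called 42 and limma voom 0. Between control females and control males edgeR called 0 of 32921 features, with 1772 at an unadjusted p under 0.05, while DESeq2 called 20 and limma voom 0.

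The upstream and downstream comparisons shared their control libraries. In females 7 sequences rose at both sites (0.0219 expected for independent lists) and 0 fell by edgeR at both, and fold changes over 33700 features correlated at r = 0.468 with a covariance of 0.0847, against r = 0.602 and a covariance of 0.112 in simulated unchanged groups with shared controls. In males 30 rose and 6 fell at both sites (0.208 and 0.0829 expected), with r = 0.72 and a covariance of 0.139, against 0.614 and 0.106 simulated. The observed covariance was thus below the simulated one in females and above it in males. When the controls were divided so that each site had its own 4, the mean over 10 divisions was r = -0.00666 with a covariance of -0.00412 in females and r = 0.0952 with a covariance of 0.0628 in males, and 1 sequence rose at both sites in each sex. Over the divisions the covariance ran from -0.035 to 0.0241 in females and from 0.043 to 0.0828 in males. Sets of 4 controls add noise that lowers r by itself, so the fall in r does not measure the part of the shared controls. Features are not independent replicates, so no p-value is given for these correlations.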

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

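The tests of temperature, replicate number, muscle tissue and oligodendrocyte RNA given here, and the fits with muscle markers as a covariate or without the libraries highest in them, were chosen after the results were seen. In the 2 groups of 8 controls, 72 values each were examined for a library far from the rest, and 24 of 144 were past Dixon's 95% critical value. The genes examined were mostly a part of those named in the text, and the set was drawn up after their values were seen. Chance alone sets apart about 1 in 20 groups, and values within a library are not independent. In larger groups no such test was made.

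Among control females, replicate 12 stood apart in muscle, with ckmb at 628 CPM (next 194), pvalb3 at 425 CPM (next 141) and the muscle sum at 3560 CPM (next 1490). Replicate 9 had vtg1 at 180 CPM (next 0.753) and a liver marker sum of 1620 CPM (next 462). Replicate 15 had the highest CYP1A, at 1.59 CPM (next 0.971), and ciarta at 4.92 CPM (next 2.21). Replicate 1 had a pituitary hormone sum of 38 CPM (next 19.7) and a microglia and macrophage sum of 5310 CPM (next 2850).

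Among control males, replicate 2 was far from the others in ckmb at 1400 CPM (next 279), pvalb3 at 654 CPM (next 45.6), acta1b at 37.3 CPM (next 8.73), fbxo32 at 11.5 CPM (next 6.79), vtg1 at 0.779 CPM (next 0.0517), the muscle sum at 7630 CPM (next 1140) and the meninges and matrix sum at 2260 CPM (next 931). Replicate 4 had hmgcra at 142 CPM (next 91.7), sqlea at 67.9 CPM (next 41.1) and dnaja at 15.6 CPM (next 12). Replicate 13 had brain aromatase (LOC120477771) at 2140 CPM (next 831), replicate 14 trib3 at 10.2 CPM (next 9.17), and replicate 5 a pituitary hormone sum of 329 CPM (next 29.3). Replicate 3 had the lowest total, 11.6 M (next 18.1 M), and purg at 11.6 CPM (next 6.95).

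The response to exposure differed between the sexes, by the interaction test, in 6 sequences. For downstream against upstream the female minus male log2 fold change of the fast myosin heavy chain LOC120486462 was -10.53 (SE 1.81, adjusted p = 0.022). It averaged 63.4 ± 152 CPM in upstream females, with 493 CPM in replicate 11, against 0.127 CPM in downstream females, 1.79 CPM in upstream males and 5 CPM in downstream males. For upstream against control the difference was -8.18 for LOC120463041, which averaged 22.2 ± 17.4 CPM in control and 1.23 ± 1.25 CPM in upstream females but 0.994 ± 0.872 CPM in control and 16.4 ± 17.5 CPM in upstream males. It was -6.87 for each of the 2 sequences of LOC120492801, and -3.71 for both gamma-crystallin N-A genes, LOC120482741 and crygn1, whose values were equal. Among splits of the same samples 19 of 40 gave at least the 1 call of downstream against upstream, the highest other giving 267, so chance was not excluded. What lay behind the 267 calls was not tested. For upstream against control 3 of 40 splits gave at least the 5 calls, with a highest other of 24, and for downstream against control, with 0 calls by edgeR, all 40 did, with a highest other of 3. Chance was not excluded for either. The last of these had 1459 sequences at an unadjusted p under 0.05, and DESeq2 called 42 and limma voom 0.

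In all 6 exposure comparisons only the real split of 80 gave as many calls, but splits ignore shared cages and number ranges. In females the counts were 8, 16 and 126 for downstream against upstream, then upstream and downstream against control (highest others 2, 9 and 2). In males they were 25, 112 and 171, with highest others of 2, 10 and 7. Without 1 library the 8 and 16 fell to as few as 1. For control females against control males all 80 splits gave at least the 0 calls of edgeR (1772 at an unadjusted p under 0.05, 20 by DESeq2, 0 by limma voom), with a highest other of 5. The calls shared by both sexes, 3, 9 and 39, had a highest other of 0 in 80 paired splits. Other splits called few sequences, so sharing itself was not tested. For called lists chance was not excluded. As many were called in 31, 5 and 46 of 80 splits for the female comparisons (9, 13 and 8 lists, highest others 16, 15 and 17) and in 26, 6 and 9 of 80 for the male ones (10, 14 and 13 lists, highest others 16, 16 and 15). Each list therefore rests on its test with an estimated correlation and on its own splits. Of 80 splits, 1 gave as small a p for the heat shock list in both sexes downstream against upstream and upstream against control, and 1 for the aryl hydrocarbon receptor list, which rests on CYP1A, in each comparison with controls. For the sterol list it was 1 in each comparison with controls except upstream females, with 4, and 3 in females and 30 in males downstream against upstream. For immediate early genes it was 1 and 3 upstream and 2 and 2 downstream against control, in females and males, and 18 in males downstream against upstream. For muscle markers it was 1 in downstream females but 13 in downstream and 17 in upstream males, and 5 in females downstream against upstream. It was 5 and 3 for proliferation in upstream and downstream males, and 2, 4 and 5 for the glucocorticoid list in upstream females, downstream females and downstream males.

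Heat shock genes were lower downstream than upstream (adjusted p = 0.0418 in females and 0.0746 in males with an estimated correlation) and higher upstream than in controls (0.0286 and 0.0874). The list did not pass downstream against control. With thinned counts the less negative of the 2 sexes' list medians was -0.25, but thinning keeps gene shares and so cannot test depth. The libraries also split by replicate number. On the first principal component, numbers 1 to 8 lay apart from later ones without overlap in the upstream and downstream groups of both sexes and in control males, and the direction was opposite in controls. The change from earlier to later numbers differed between upstream and control fish in 2078 sequences in females and 1535 in males. Between downstream and control fish it differed in 426 and 3181, and between the sites in 4 and 2. The numbers may mark batches of fish or of libraries, which the labels do not name. Among numbers 9 and over the less negative of the 2 list medians was -0.35, and among numbers 1 to 8 the medians were -0.13 in females and -0.2 in males. The value in the later numbers argues against a factor shared by the later libraries of both sites as the whole cause, as does a median of -0.25 with a surrogate variable. A factor in the later upstream libraries alone was not excluded by either.

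Warmer water upstream as a cause of the heat shock difference was tested on the cold-inducible RNA-binding protein genes, which heat lowers, so that all would be higher downstream. The lowest log2 fold change among the most abundant sequences of cirbpa and cirbpb in both sexes was -0.14 (cirbpa in females, SE 0.08, adjusted p = 0.68), against -0.02 (SE 0.07) in males, while cirbpb was at 0.14 (SE 0.07) in females and 0.29 (SE 0.08) in males. Another cirbpa sequence was called in males, up by 0.86 (adjusted p = 0.028, gene sum 0.27), which is the direction that warmer water upstream would give. A bound of 0 on the lowest value was set first. It was widened to 2 SE after the values were seen, because the lowest value lay within its error of 0, and the test then left temperature open. The labels give no water temperature at the sites, so a warmer upstream site, other proteotoxic differences between the sites and an unnamed batch of the later upstream libraries may each be a cause, and these are hypotheses.

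Muscle genes were lower downstream than in controls, with the list at adjusted p = 0.0187 in females and 0.366 in males with an estimated correlation. Over control libraries the members of the muscle list rose and fell together, with a median pairwise Spearman correlation of 0.88 in females and 0.9 in males, and 2 of 8 female and 3 of 8 male control libraries lay within the range of the downstream libraries, with 1 more male below it. Both go with muscle tissue carried into some samples at dissection, which may account for the difference. A response of muscle-like genes in brain was not tested separately.

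Sterol synthesis genes were higher at both sites than in controls, although in upstream females 0 of 27 members were called by edgeR over all features and the list had adjusted p = 0.126 with an estimated correlation. The lowest of the 4 list medians was 0.24 with thinned counts, which likewise cannot test depth. It was 0.2 with a surrogate variable, which leaves open a factor tied to exposure. Oligodendrocytes make much of the brain's cholesterol, yet the highest of their list's 4 medians was 0.08, which argues against more of their RNA. Exposure to the water at both sites may have raised the pathway, and so may a difference in handling or food between exposed fish and controls, which the labels do not describe.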

How the results depend on the processing

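Of the settings below, the muscle marker sum as a covariate, the removal of libraries high in it or of low correlation, thinned counts, lists by symbols only, the samples of the replicate block without the block, and low or high replicate number as a covariate were chosen after the results were seen. Over all settings 440 fold changes of named genes lost their call, 2 gained one and 8 called ones changed sign. The other 1710 may include sign changes of uncalled genes. The gains were fkbp5 by DESeq2, at 1.23 upstream and 1.41 downstream against control males. Unless a reason is given, the cause was not tested. Other pseudocounts and filters for normalized values had no value, because the files hold counts.

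DESeq2 called 259, 255 and 466 sequences for downstream against upstream, upstream against control and downstream against control in females, and 213 and 549 in males for the first pair. For called features, male downstream vs control stood at 806 by DESeq2. It called 20 between control females and males, and 23, 58 and 42 interactions in the same order. It shared 62, 50 and 161 calls between the sexes, and 72 in females and 239 in males between the sites. It also made more false calls on simulated data. Its size factors within edgeR gave 13 for females downstream against upstream. Limma voom called 63 and 29 in females downstream against upstream and upstream against control, 98 in males downstream against upstream, and 0 interactions for downstream against upstream and 0 for upstream against control, with edgeR at 1 and 5.

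With a mean CPM of at least 1 the count for females downstream against upstream was 45, with 9 shared between the sexes. With no filter on low counts, which adds tests, it was 1 for females upstream against control, 1 for control females against males and 4 for the interaction of downstream against upstream. With the 3 groups in 1 fit there were 128 and 32 calls in females, downstream against upstream and upstream against control, and 47, 244 and 342 in males. With 1 surrogate variable there were 70, 54 and 242 in females and 112, 197 and 289 in males.

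With transcripts summed per gene there were 170 calls in males upstream and 280 in males downstream against control. The sign changed for zc2hc1a (-0.04), eif3c (0.01 in females, 0.05 in males), celf3b (0), paqr6 (-0.09), khdrbs1a (-0.02) and bcl9 (-0.04), because other sequences of those genes did not follow the called one.

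With the muscle marker sum as covariate there were 4 calls in females downstream against control, 44 in males downstream against upstream, 29 in males upstream and 17 in males downstream against control, and ckma in females changed sign, to 0.07. Without libraries high in muscle markers there were 2 and 70 calls in females upstream and downstream against control, and 46 and 78 in males. Without libraries under 0.5 of the median total there were 1 and 81 in females, from fewer samples.

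With low (1 to 8) or high replicate number as a covariate there were 103 and 25 calls in females, downstream against upstream and upstream against control, and 113, 56 and 76 in males. It kept all 8 and 25 calls between the sites, and the heat shock medians were -0.23 in females and -0.27 in males. Of the calls of named genes against controls, 20 were lost. Against controls 1 covariate fits less well, because the ranges differ in opposite directions in controls and exposed fish. Groups share some replicate numbers, 4 to 6 per comparison. Over the libraries that share a number the median correlation of residual expression ran from -0.07 to 0.088, so the numbers do not pair the fish. With a replicate block there were 0, 0 and 4 calls in females and 0, 0 and 0 in males by edgeR, and the same samples without the block gave 0, 3 and 20 in females and 0, 0 and 57 in males.

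With an estimated correlation 1, 3 and 5 lists were called in females and 0, 2 and 3 in males, against 9, 13 and 8 and 10, 14 and 13 with the preset one. Of 67 called lists 14 were kept. With lists by symbols only 63 were kept, and the aryl hydrocarbon receptor list, called in 4 comparisons, had no value because 2 tested members were left.

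Leaving out 1 library moved many counts. For females downstream against upstream (8 calls) the count ran from 1, without female downstream replicate 2, to 89, without female upstream replicate 7. It was 5, 5, 2, 3, 1 and 13 without downstream replicates 6, 8, 10, 15, 16 and 17, and 28, 13, 34, 5, 1, 1, 1 and 1 without upstream replicates 1, 4, 6, 10, 14, 19, 22 and 23. For females upstream against control (16 calls) it ran from 1, without female control replicate 8, to 28, without female upstream replicate 1. It was 2, 2, 1, 1, 6, 1 and 1 without control replicates 1, 6, 9, 10, 12, 15 and 16, 10, 27 and 2 without upstream replicates 6, 7 and 10, and 1 without upstream replicates 4, 11, 14, 16, 19, 22 and 23. For females downstream against control (126) it ran from 56, without female control replicate 9, to 126, without female downstream replicate 24. It was 77, 70 and 81 without control replicates 10, 12 and 15, and 78, 76, 70, 77 and 79 without downstream replicates 2, 10, 14, 15 and 16.

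For males downstream against upstream (25) it ran from 5, without male downstream replicate 9, to 78, without male upstream replicate 5. It was 10, 7, 7, 6, 7 and 39 without downstream replicates 3, 5, 7, 11, 12 and 23, and 59, 74, 45, 8, 8, 7, 12, 6, 7, 6, 6 and 7 without upstream replicates 2, 3, 8, 9, 12, 13, 15, 17, 18, 20, 21 and 24. For males upstream against control (112) it ran from 29, without male control replicate 7, to 173, without male upstream replicate 8. It was 46, 31 and 68 without control replicates 2, 5 and 13, and 73, 71, 58, 63, 57, 73 and 74 without upstream replicates 2, 9, 13, 17, 18, 20 and 24. For males downstream against control (171) it ran from 65, without male downstream replicate 9, to 207, without male control replicate 14. It was 78, 112, 68 and 94 without control replicates 2, 3, 5 and 7, and 70, 74, 76, 106 and 111 without downstream replicates 3, 7, 11, 18 and 19. The counts of calls thus depended on the number and choice of libraries.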

Other observations

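No hypothesis is added in this part. Circadian clock genes (38 tested) were called as a list in upstream females (median 0.165, 5 higher and 1 lower when adjusted over the list alone, adjusted p = 0.0194, and adjusted p = 0.578 with an estimated correlation), in males downstream against upstream (median 0.121, 4 higher and 1 lower, adjusted p = 0.0239, and adjusted p = 0.595 with an estimated correlation) and in males downstream against control (median 0.135, 3 higher, adjusted p = 0.000787, and adjusted p = 0.306 with an estimated correlation). The melatonin synthesis gene aanat2 was lower when adjusted over the list alone in upstream (-2.29) and downstream (-2.8) females against controls. In upstream males the clock activator gene npas2 rose by 0.59 (adjusted p = 0.021).

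Endoplasmic reticulum stress genes (22 tested) were called as a list in females downstream against upstream (median -0.218, 4 lower when adjusted over the list alone, adjusted p = 0.000797, and adjusted p = 0.821 with an estimated correlation), in males downstream against upstream (median -0.178, 2 lower, adjusted p = 0.000389, and adjusted p = 0.637 with an estimated correlation), in upstream females against controls (median 0.225, adjusted p = 0.00692, and adjusted p = 0.578 with an estimated correlation) and in upstream males against controls (median 0.228, adjusted p = 0.000359, and adjusted p = 0.467 with an estimated correlation). The chaperone gene hspa5 was lower downstream than upstream in both sexes when adjusted over the list alone, by 0.65 in females and 0.76 in males, and not over all features.

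Mitochondrially encoded genes (13 tested) had a median of -0.278 in upstream males against controls, with ND6 at 23.1 against 38.9 CPM falling over all features and 8 lower when adjusted over the list alone (adjusted p = 1.9e-09, and adjusted p = 0.159 with an estimated correlation). In downstream males the median was -0.246 with 2 lower (adjusted p = 4.88e-05, and adjusted p = 0.416 with an estimated correlation). Respiratory chain genes (72 tested) passed in all 6 exposure comparisons with small medians, -0.0693, 0.132 and 0.0743 in females for downstream against upstream, upstream against control and downstream against control (adjusted p = 0.00549, 8.49e-08 and 0.00398) and 0.0634, -0.172 and -0.103 in males (adjusted p = 0.0321, 6.06e-07 and 0.00901). None of these passed with an estimated correlation (adjusted p = 0.578 or more). Ribosomal protein genes (92 tested) had medians of -0.0681 in females downstream against upstream (adjusted p = 0.0256, and adjusted p = 0.821 with an estimated correlation), -0.212 in upstream males (adjusted p = 2.69e-10, and adjusted p = 0.519) and -0.217 in downstream males against controls (adjusted p = 2.17e-07, and adjusted p = 0.692).

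Further lists passed as follows. Proliferation genes had a median of 0.227 in females downstream against upstream with 0 members called by edgeR (adjusted p = 0.00966, and adjusted p = 0.821 with an estimated correlation). Interferon genes had a median of -0.232 in upstream females, with irf7 lower when adjusted over the list alone (adjusted p = 0.00692, and adjusted p = 0.578). GABA and glutamate genes had medians of 0.105 in males downstream against upstream (adjusted p = 0.00332, and adjusted p = 0.637) and 0.0932 in males downstream against control (adjusted p = 0.0438, and adjusted p = 0.692). Xenobiotic metabolism genes had a median of -0.186 in upstream males, with ephx1 lower when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.159), and oxidative stress genes a median of -0.0505, with gpx4a the 1 call over all features and 1 higher and 6 lower when adjusted over the list alone (adjusted p = 0.0221, and adjusted p = 0.467). The second value of each pair is with an estimated correlation.

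The remaining 12 lists were called in none of the 6 exposure comparisons with the preset correlation. Their lowest adjusted p values were 0.053 for estrogen signalling, 0.0694 for oligodendrocytes, 0.084 for neurons, 0.15 for radial glia and astroglia, 0.154 for reproductive neuroendocrine genes, 0.155 for metal response, 0.17 for hypoxia, 0.206 for the thyroid axis, 0.248 for appetite peptides, 0.365 for monoamine systems, 0.413 for pituitary hormones and 0.739 for DNA damage. The yolk genes vtg1 and vtg3 were lower in females downstream than upstream when adjusted over the list alone, where vtg1 averaged 402 ± 1230 CPM upstream. That mean rested on upstream replicate 11, with vtg1 at 4120 CPM and a liver marker sum of 6570 CPM. The zinc exporter gene slc30a1a rose in upstream (0.49, adjusted p = 0.038) and downstream (0.51, adjusted p = 0.023) males against controls, and the kinase gene plk3 in downstream females (0.36, adjusted p = 0.027).

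Between control females and control males 10 lists passed with the preset correlation and none with an estimated one, where the lowest adjusted p was 0.627, and no member was called over all features. Ribosomal proteins (median -0.301, adjusted p = 5.9e-17), the respiratory chain (-0.231, 2.92e-13), mitochondrially encoded genes (-0.235, 6.58e-05) and meninges and matrix (-0.457, 0.000694) had the smallest adjusted p. The others were oxidative stress (0.00376), sterol synthesis (0.0133), heat shock and monoamine systems (both 0.0297), microglia (0.0381) and eye and pineal markers (0.0421).

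Over all libraries the first 2 principal components of log2 CPM held 8.6% and 6.4% of the variance. The authors' deposited tables called 309, 275 and 565 sequences in females for downstream against upstream, upstream against control and downstream against control, and 239, 620 and 925 in males, at the same threshold. Every sequence called here was among these, in the same direction.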
